A study of Mus musculus with 12 samples.

How the data were processed

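Whole mouse lungs were dissociated by enzymatic digestion at 37 °C, passed through a 40 µm filter, depleted of red cells and loaded on a 10x Genomics droplet system, per the labels' protocols, giving 1 library for each of 12 samples in 4 groups of 3. The series design speaks of separate mice, so the spread between libraries of a group is read as spread between animals. The deposited values are raw UMI counts per gene and barcode (27998 genes), made by the authors with Cell Ranger; the file headers give version 5.0.0, while the submitters' processing notes give Cell Ranger 3.0.1 with STAR, Seurat 3.0.2 and the mouse build mm10. How the barcodes were called as cells is not given in the sources used here. Coordinates are from GENCODE vM21 on GRCm38/mm10 and cover whole protein-coding genes, placed by Ensembl identifier. The replicate numbers in the labels were used as names. Replicates of 1 group were compared before averaging, and all differed by far more than sampling noise (chi-square per degree of freedom 49.4 to 1519).

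The groups, comparisons, tests, gene lists, cell type markers and most alternatives were fixed before the data were examined. Barcodes were kept with at least 200 detected genes and at most 20% of UMIs from mitochondrial genes, which left 138511 of 147021. Doublets were called per library from 2 simulated doublets per cell and removed, 4722 in all, 1.66 to 7.73% per library, where loading predicts 7.7 to 11.3% and where 26.9 to 58.1% of the simulated doublets were detected, so some doublets remain. The 133789 cells of all libraries were clustered together (2000 variable genes, 30 principal components, 15 neighbours, Leiden at resolution 1.0) with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, scikit-image 0.26.0 and igraph 0.11.9, without integration across libraries. Of 63 clusters 39 were given a class from 20 sets of fixed markers. A marker counted where at least 20% of the cluster's cells held it, at least 4-fold above the median cluster and at no less than 10% of its highest cluster; a name needed at least 3 markers and 50% of the set. Of the markers 3, Ighd, Trac and Trbc2, had no feature of that name. These thresholds were set after clusters were seen, and clusters named through them include cluster 14 (neutrophils), which held 6.89% ± 0.562 of the cells in control, 1.62% ± 2.64 in LPS, 0.0863% ± 0.0768 in LPS+Dex and 0.0410% ± 0.0314 in LPS+TMP. The others were cluster 24 (secretory; 1.45, 1.01, 0.383 and 1.14% in that order), cluster 44 (platelet; 0.295, 0.736, 0.266 and 0.0655%), cluster 23 (ciliated; 1.78, 1.23, 0.424 and 0.567%) and cluster 39 (mural; 0.764, 0.598, 0.173 and 0.345%). Unnamed clusters held 11.9% ± 3.62, 9.57% ± 4.49, 6.34% ± 2.62 and 8.01% ± 1.10.

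For gene levels, UMI counts were summed per library and class in 6 classes, each with at least 20 cells in all 12 libraries, and tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr and the quasi-likelihood F test in 1 fit of 4 group means over 12 libraries, with 8 residual degrees of freedom. P-values are two-sided and Benjamini-Hochberg adjusted within class and contrast, with a threshold of 0.05. CPM values of single genes are scaled by TMM, and log2 fold changes carry the SE of the fit. Summed markers of other classes, sums of Hspa1a and Hspa1b, and comparisons of endothelial with B cell levels use CPM without TMM. Class sizes were tested with the same model on the number of cells in 18 classes averaging at least 10 cells per library, with the total of kept cells as offset, and over the 4 groups with an exact permutation test of all assignments of libraries to groups. Shares sum to 100%, so a rise of 1 class lowers the others. Dissociation recovers cell types unequally and this can set shares.

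Gene lists, 33 fixed and 32 with at least 5 measured genes in some class, were tested with limma 3.58.1 camera at a preset correlation between genes of 0.01, adjusted over lists and classes within a contrast; 4 list genes (Ccn2, Cebpd, Cxcl11 and Mx2) had no feature of that name. None of the list calls held with the correlation estimated from the data. Named genes followed a rule: per contrast and class the 3 largest rises and 2 largest falls (2 rises and 1 fall for LPS+TMP against LPS+Dex) among called genes whose libraries did not overlap between the groups, with at least 50 CPM in the higher group and at least 0.5 of the CPM of all cells there, without gene models, ribosomal, mitochondrial, haemoglobin, sex-linked and receptor segment genes and markers of other classes. List members with the largest change among the called, or the highest level where none was called, serve as examples. Markers of other classes are given as a measure of background, since free RNA and mixed droplets bring RNA of abundant cells into every class.

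The tests were tried on simulated counts with known changes. Genes were drawn independently around control means, without a library like LPS replicate 2, and the simulated share changes were all rises. The rates below may therefore not carry over to these data. For LPS against control, 4-fold changes were found for 88.3 to 98.8% and 2-fold changes for 30.4 to 85.4% of the changed genes in the 6 classes, fewest in neutrophils, and 2.2 to 4.6% of the calls were false; for shares 73.3% of 4-fold changes were found over 50 simulations. Alternatives were DESeq2 1.42.0, DESeq2-type size factors in edgeR, no filter on low counts, a stricter cell filter (500 genes, 10% mitochondrial UMIs), called doublets kept, a Leiden resolution of 0.5, TMM scaling of class counts, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were all results without LPS replicate 2 that the plan had not named, shares among structural cells, the alternatives of the test over 4 groups, and B, T and NK cells. Correlations of fold changes were set beside 20 simulations of the same libraries without group effects, also without LPS replicate 2. Figures were drawn with matplotlib 3.10.9.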

Results

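Lungs of mice with acute lung injury were profiled by single-cell RNA sequencing in 12 libraries, which the series design assigns to 12 mice in 4 groups of 3. One group was the control. The second received lipopolysaccharide (LPS, a component of the outer membrane of Gram-negative bacteria that provokes lung inflammation) by intraperitoneal injection at a stated 30 mg/ml. The other groups received dexamethasone (Dex, a synthetic glucocorticoid) at 5 mg/ml or TMP (ligustrazine, also called tetramethylpyrazine, a plant alkaloid) at 50 mg/ml 1 h before LPS. Lungs were collected after 72 h. The doses are stated as concentrations, so amounts per body weight were not used here. The files held 147021 barcodes, 10404 to 14725 per library. They carried 70344559 to 146716620 unique molecular identifiers (UMIs) per library. After filtering and removal of called doublets 133789 cells were left, 9404 to 13417 per library, with a median of 3598 to 7974 UMIs per cell. The median was lower in the control libraries (3598, 3672.5 and 3650.5 UMIs) than in all 9 libraries of the other groups (4210 to 7974 UMIs). Although the labels name the cells as epithelial, most of them carried markers of leukocytes, as the shares of cells show. Classes were built here from clusters and fixed markers, and each class name stands for cells like that type.

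The shares of cells answer which populations of the lung gained or lost ground after LPS and after each pretreatment. Over the 4 groups, the shares of 8 of 18 classes differed in an exact permutation test over all assignments of the libraries to groups. P-values were adjusted over the classes. The lowest adjusted exact p belonged to endothelial cells (0.00351) and platelets (0.00643), followed by alveolar type 2 cells (0.0257), which make surfactant. Ciliated cells, fibroblasts, monocyte-macrophages and B cells each had an adjusted exact p of 0.0292, and dendritic cells 0.0307. This count of 8 was 4 without control 1, 1 without control 2 or control 3, 1 without LPS+Dex 1 or LPS+Dex 2, 2 without LPS+Dex 3 and 1 without LPS+TMP 2.

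Between LPS and control, the mean share of monocyte-macrophages was 18.1% ± 4.26 (SD, n = 3) against 9.69% ± 2.03. That of neutrophils was 16.8% ± 13.1 against 7.14% ± 0.522 and that of NK cells 10.4% ± 5.11 against 4.10% ± 0.821. Alveolar type 2 cells made up 0.741% ± 0.433 of the cells after LPS and 1.68% ± 0.351 in control. Dendritic cells made up 1.66% ± 0.952 and 3.45% ± 0.303. With edgeR on the cell counts 0 of 18 classes passed the adjusted threshold and 6 had an unadjusted p under 0.05. The lowest adjusted p was 0.130, for NK cells (log2 fold change 1.34 ± 0.45, SE). An exact permutation test of 3 against 3 libraries cannot go below a two-sided p of 0.10. LPS replicate 2 had 14.6% T cells and 16.2% NK cells, the highest of the LPS libraries, and 5.68% neutrophils, the lowest. Without it 6 classes passed: alveolar type 2 cells (log2 fold change -1.74), T cells (-1.58), dendritic cells (-1.49), monocyte-macrophages (1.07), neutrophils (1.65) and plasma cells (3.10). Without LPS replicate 3 only 1 class did.

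**Figure D1:**
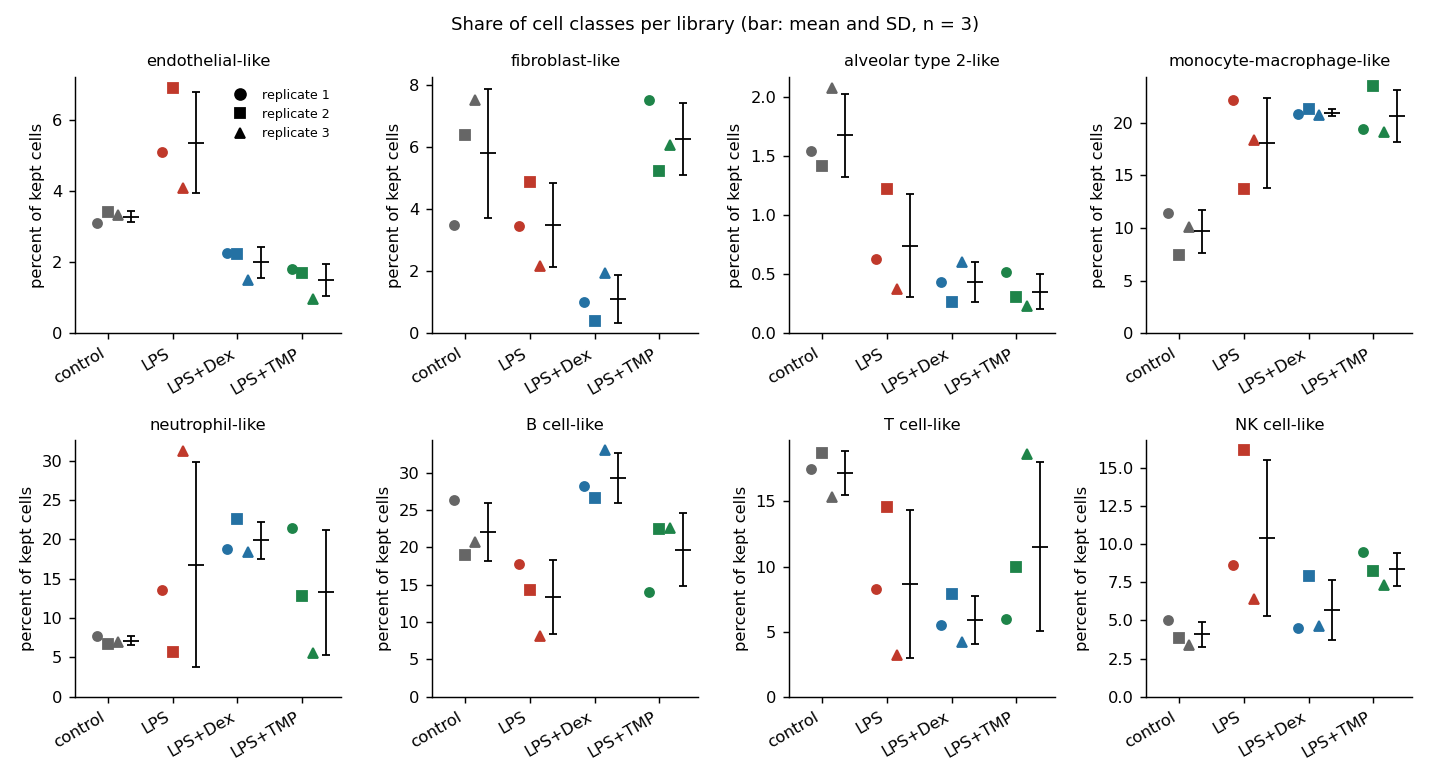
Share of 8 cell classes in each library, in percent of the kept cells, by group; each symbol is 1 library and the bar gives the mean and SD of 3 libraries. Endothelial cells averaged 5.37% in LPS, 2.00% in LPS+Dex and 1.50% in LPS+TMP, and fibroblasts 3.49%, 1.11% and 6.25%.

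After LPS with Dex, 8 classes differed in share from LPS alone. Alveolar type 1 cells, the thin cells of gas exchange, fell by 4.31 ± 0.87 (SE) on the log2 scale (adjusted p = 0.00176). This rests on 2, 0 and 2 cells in the LPS+Dex libraries against 21, 53 and 6 in LPS replicates 1, 2 and 3. Mural cells, a class named from markers of cells that wrap vessels, fell by 2.11 ± 0.50 (adjusted p = 0.00497), from 1.47% ± 0.751 to 0.338% ± 0.158. Cluster 39, led by Hhip and Aspn, held 38.3% ± 6.95 of this class after LPS and 50.2% ± 3.87 after LPS with Dex. The class may therefore hold more than cells around vessels. Endothelial cells fell from 5.37% ± 1.43 to 2.00% ± 0.441 (adjusted p = 0.0187). Fibroblasts fell from 3.49% ± 1.36 to 1.11% ± 0.773 and ciliated cells from 1.23% ± 0.270 to 0.424% ± 0.223 (both adjusted p = 0.0236). B cells rose from 13.4% ± 4.90 to 29.3% ± 3.34 (adjusted p = 0.0448). Platelets and basophils or mast cells fell (both adjusted p = 0.0492). Of the 8 calls 1, that of mural cells, was left without LPS replicate 2, where alveolar type 1 cells were too few to test. Without LPS+Dex 1, LPS+Dex 2 and LPS+Dex 3 the count was 4, 3 and 4. As a share of the structural cells alone, a denominator added after these values were seen, endothelial cells (log2 fold change 0.01), fibroblasts (-0.51) and ciliated cells (-0.41) no longer passed.

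After LPS with TMP, platelets fell from 0.736% ± 0.331 to 0.0655% ± 0.0621 of the cells (log2 fold change -3.44 ± 0.65, SE, adjusted p = 0.000848). This rests on 15, 5 and 1 cells in LPS+TMP replicates 1, 2 and 3 against 50, 78 and 132 in those of LPS. Endothelial cells fell from 5.37% ± 1.43 to 1.50% ± 0.449 (-1.85 ± 0.42, adjusted p = 0.00348), with no overlap between the libraries of the groups. Against LPS with Dex, LPS with TMP held more fibroblasts (6.25% ± 1.15 against 1.11% ± 0.773, log2 fold change 2.49 ± 0.55, adjusted p = 0.00481). It also held more mural cells (1.33% ± 0.267 against 0.338% ± 0.158, 1.96 ± 0.50, adjusted p = 0.00929) and fewer platelets (-1.97 ± 0.64, adjusted p = 0.0376). The LPS+Dex libraries held 50, 24 and 25 platelets. Among structural cells alone, endothelial cells stayed lower after TMP than in LPS (log2 fold change -1.53). There 3 further classes passed, fibroblasts (1.18), ciliated cells (-0.84) and alveolar type 1 cells (-1.45).

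Gene levels were compared within 6 classes, by summing the UMIs of each class per library. Of the LPS libraries, replicate 2 lay nearest to the controls in all 6. On a line from the control mean (0) to the mean of the pretreated LPS libraries (1), each library was placed over the genes called the same way in LPS+Dex and LPS+TMP against control. LPS replicate 2 lay at 0.138 in endothelial cells, 0.204 in alveolar type 2 cells, 0.223 in fibroblasts, 0.318 in monocyte-macrophages, 0.400 in alveolar macrophages and 0.440 in neutrophils. The other LPS libraries lay between 0.688 and 1.30, and the controls between -0.026 and 0.285. In alveolar macrophages LPS 1 (0.688) lay nearer to LPS 2 than to LPS 3 (1.30). In alveolar type 2 cells alone LPS+TMP replicate 3 also lay low, at 0.155. Leaving out each library in turn was planned, and counts of called genes that involve the LPS group are given below without this library.

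**Figure D2:**
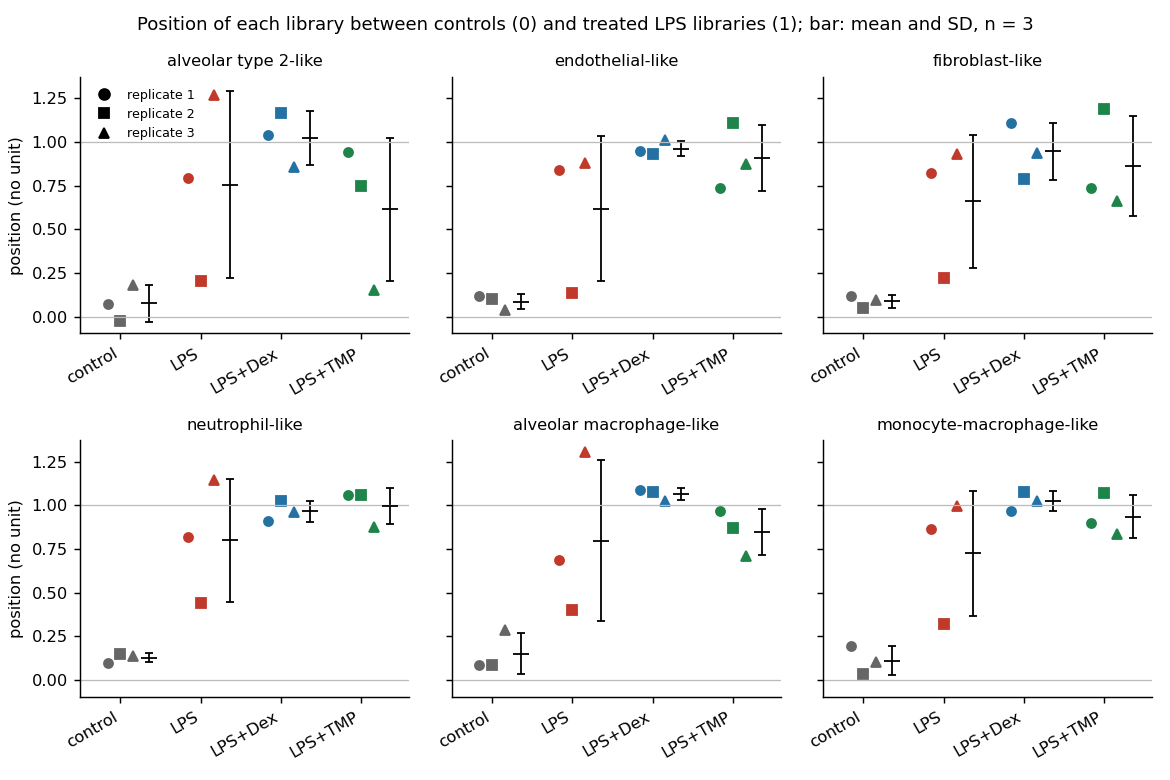
Position of each library, without unit, on the line between the controls (0) and the pretreated LPS libraries (1) in 6 classes; symbols are libraries and bars give the mean and SD of 3. LPS replicate 2 lies at 0.138 to 0.440 and the other LPS libraries at 0.688 to 1.30.

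In endothelial cells (96 to 744 cells and 485777 to 2933439 UMIs per library) LPS raised genes of antigen presentation by MHC class I, the molecules that display peptides to CD8 T cells. H2-Q7 (ENSMUSG00000060550, chromosome 17, 35439155 to 35443773, GRCm38/mm10, a protein-coding gene like all genes placed here) rose from 212 ± 20.9 to 644 ± 179 CPM (counts-per-million; SD, n = 3; log2 fold change 1.60 ± 0.19, SE, adjusted p = 0.00611). Its close copy H2-Q6 (ENSMUSG00000073409, chromosome 17, 35424850 to 35430055) rose by 1.55 ± 0.22 (adjusted p = 0.0133). Counts can be split between such copies. Of 15 measured genes of the MHC class I list, 5 rose and none fell (9 adjusted over the list alone), among them H2-K1 (ENSMUSG00000061232, chromosome 17, 33996017 to 34000347; 1.09 ± 0.16). The list rose with a median of 0.82 (limma camera, adjusted p = 6.78e-20; adjusted p = 0.32 with an estimated correlation). Fam198b (ENSMUSG00000027955, chromosome 3, 79884533 to 79946280) also rose (1.31 ± 0.24, adjusted p = 0.0437). The 25 cell cycle genes had a median of 2.62 (adjusted p = 2.39e-15; adjusted p = 0.448 with an estimated correlation). Of them 0 were called over all genes by edgeR and 21 were higher adjusted over the list alone. Genes of aerocytes, the specialised alveolar capillary cells, had a median of -0.68 (adjusted p = 2.95e-07; adjusted p = 0.435 with an estimated correlation). Of 10 such genes 0 were called and 4 were lower adjusted over the list alone. Cluster 30, led by Tbx3 and then by the aerocyte gene Ednrb, held 37.4% ± 5.60 of the endothelial cells in control and 21.0% ± 6.97 after LPS. Markers of neutrophils measured in this class were 459 ± 510 CPM in control and 4495 ± 6674 CPM after LPS. NK cell markers were 38.1 ± 22.9 and 163 ± 34.3 CPM (0 of 1 called). In all, edgeR called 11 genes higher and 7 lower of 9599 (adjusted p under the 0.05 threshold). The 18 calls became 0 without control 1, 1 without control 2, control 3 or LPS 3, and 677 without LPS 2. Among the latter all 18 remained. H2-Q7 lost its call in 2 of 12 alternatives, H2-Q6 in 4 and Fam198b in 6 of 11.

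Fibroblasts (43 to 855 cells, 361662 to 6392367 UMIs per library) showed the same gene group higher after LPS. H2-D1 (ENSMUSG00000073411, chromosome 17, 35262730 to 35267499) rose from 502 ± 19.6 to 1589 ± 477 CPM (log2 fold change 1.66 ± 0.20, adjusted p = 0.00728). B2m, the invariant chain of MHC class I (ENSMUSG00000060802, chromosome 2, 122147686 to 122153083), rose from 884 ± 18.9 to 2336 ± 537 CPM (1.40 ± 0.17, adjusted p = 0.00728). In the MHC class I list 4 of 15 genes rose (14 adjusted over the list alone), with a median of 1.33 (camera adjusted p = 1.09e-19; adjusted p = 0.365 with an estimated correlation). Saa3, an acute-phase serum amyloid (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), rose from 31.7 ± 30.9 to 2343 ± 1868 CPM (6.18 ± 0.98, adjusted p = 0.0408). Complement factor B, Cfb (ENSMUSG00000090231, chromosome 17, 34856374 to 34862518), rose from 40.5 ± 5.82 to 159 ± 36.8 CPM (1.98 ± 0.26, adjusted p = 0.0117). H2-Q7 rose by 3.13 ± 0.50 (adjusted p = 0.0408). Among 14 acute-phase and epithelial defence genes 1 rose, Saa3 (10 adjusted over the list alone; median 1.48, camera adjusted p = 4.4e-06; adjusted p = 0.448 with an estimated correlation). Interferon-stimulated genes had a median of 0.90 over 24 genes (adjusted p = 3.95e-10; adjusted p = 0.448 with an estimated correlation). Of them 1, Isg15 (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818), rose, by 1.34 ± 0.21, and 11 were higher adjusted over the list alone. Genes of the unfolded protein response had a median of -0.37 (adjusted p = 2.03e-06; adjusted p = 0.32 with an estimated correlation). Of 15 genes 0 were called and 9 were lower adjusted over the list alone. Neutrophil markers in the class were 452 ± 126 CPM in control and 6009 ± 8506 CPM after LPS. NK cell markers were 16.3 ± 8.69 and 163 ± 60.6 CPM (0 of 4 called). Cluster 13 held 63.5% ± 9.89 of the class in control and 48.6% ± 4.17 after LPS, and cluster 15 the rest. Of 11986 genes, 10 rose and 0 fell by edgeR, 1875 had an unadjusted p under 0.05, and DESeq2 called 154 higher and 50 lower. The 10 calls became 6 without control 1, 0 without control 2, control 3 or LPS 3, 3 without LPS 1 and 367 without LPS 2. The calls of Saa3 and H2-Q7 were lost in 6 of 12 alternatives and that of Cfb in 5.

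In alveolar type 2 cells (23 to 236 cells, 254239 to 2122602 UMIs per library) edgeR called 0 of 6560 genes after LPS, with 531 at an unadjusted p under 0.05 and 35 higher and 5 lower by DESeq2. Without LPS 2, 57 genes were called, 56 of them higher. Acute-phase and epithelial defence genes had a median of 0.89 over 11 genes (camera adjusted p = 2.01e-06; adjusted p = 0.422 with an estimated correlation), 5 of them higher adjusted over the list alone. Lcn2, which binds bacterial siderophores (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), was at 563 ± 39.9 CPM in control and 1936 ± 1358 CPM after LPS (adjusted p = 0.151). MHC class I genes had a median of 0.59 (adjusted p = 4.4e-06; adjusted p = 0.448 with an estimated correlation), 6 of 14 higher adjusted over the list alone. Neutrophil markers in the class were at 402 ± 544 CPM in control and 9452 ± 14500 CPM after LPS. NK cell markers were at 15.2 ± 13.3 and 190 ± 105 CPM (0 of 1 called).

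Neutrophils (541 to 3838 cells, 1476043 to 29621051 UMIs per library) had 1022 genes called higher and 889 lower of 9843, the most of the 6 classes with edgeR and all libraries. By DESeq2 the count was 1971, against 2167 in monocyte-macrophages. Genes of the neutrophil immaturity list, which holds granule genes and others, were among the rises. Lcn2 went from 865 ± 331 to 7195 ± 7780 CPM (log2 fold change 3.06 ± 0.72, adjusted p = 0.0173). Cd177, Ly6g and lactoferrin (Ltf) rose by 3.02 ± 0.60, 2.92 ± 0.47 and 2.68 ± 0.66. Of the 16 genes of this list 10 rose (11 adjusted over the list alone, median 1.72, camera adjusted p = 6.88e-06, and adjusted p = 0.497 with an estimated correlation). Stfa2, a protease inhibitor of a gene family with near-identical copies, so that its counts are uncertain (ENSMUSG00000022902, chromosome 16, 36403992 to 36408457), rose by 7.24 ± 0.93 (adjusted p = 0.00382), from 18.1 ± 11.8 to 2702 ± 2556 CPM. Saa3 rose by 7.05 ± 1.28 (adjusted p = 0.0102). Ggt1 (ENSMUSG00000006345, chromosome 10, 75561604 to 75586200) had 0.510 ± 0.502 CPM in control, from 3 counts in all, and 86.2 ± 111 CPM after LPS (adjusted p = 0.0123). Its fitted fold depends on the prior count and is not given. Thbs1, thrombospondin 1 (ENSMUSG00000040152, chromosome 2, 118111876 to 118127133), fell from 1732 ± 181 to 244 ± 221 CPM (-2.84 ± 0.58, adjusted p = 0.0123). Ptgs2, the inducible cyclooxygenase (ENSMUSG00000032487, chromosome 1, 150100031 to 150108227), fell from 860 ± 6.91 to 145 ± 137 CPM (-2.59 ± 0.70, adjusted p = 0.0254). Of 22 NF-kB target genes 8 fell and 1, Ccl2, rose (10 and 1 adjusted over the list alone; median -0.64, adjusted p = 0.000293; adjusted p = 0.477 with an estimated correlation). Of 18 immediate early genes, which respond to stimuli and to tissue digestion, 8 fell and 1 rose (11 and 1 adjusted over the list alone; median -0.93, adjusted p = 7.37e-05; adjusted p = 0.477 with an estimated correlation), Dusp1 among the falls (-1.68 ± 0.46). The clusters that make up this class differed between the 2 groups. Cluster 14 held 96.5% ± 0.875 of the control neutrophils and 27.9% ± 47.0 of those after LPS, where clusters 3 and 7 held 32.7% and 27.9%. In LPS replicate 2 cluster 14 held 502 of the cells, against 23 and 1 in LPS replicates 1 and 3. Markers of other cells moved both ways in this class. Those of NK cells rose from 15.0 ± 3.07 to 62.8 ± 13.96 CPM (2 of 3 called higher) and of monocyte-macrophages from 296 ± 22.2 to 540 ± 101 CPM (1 of 12). Those of secretory cells fell from 7097 ± 520 to 3040 ± 3349 CPM (3 of 6 called lower), of alveolar type 2 cells from 471 ± 28.1 to 224 ± 35.4 CPM (3 of 8) and of erythroid cells from 1616 ± 704 to 168 ± 204 CPM (1 of 5). The median UMIs per cell were 1874.5 to 2177 in the control libraries and 2961 to 7343.5 after LPS, and the median mitochondrial share 0.42 to 0.48% and 0.58 to 1.51%. Cell make-up, cell quality and changes within neutrophils are therefore not separated here. Groups did not overlap for 31.8% of the genes, where chance gives 10%. The 1911 calls became 451, 571 and 410 without control 1, 2 and 3, 1167 and 654 without LPS 1 and 3, and 3883 without LPS 2, which include 1894 of the 1911. Stfa2, Saa3, Ggt1 and Thbs1 kept their calls in all 12 alternatives, and Ptgs2 lost its call in 4.

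**Figure D3:**
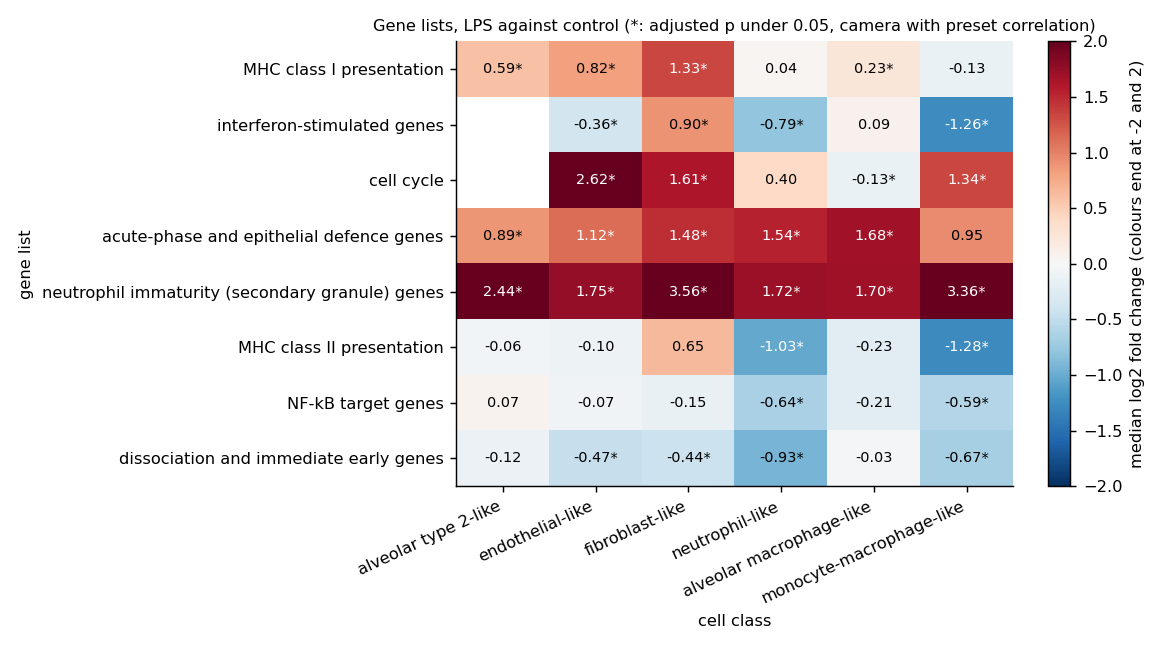
Median log2 fold change of 8 gene lists in 6 cell classes, LPS against control, as colour and number; a star marks a camera adjusted p under 0.05 with the preset correlation, and empty cells had too few measured genes. MHC class I genes had medians of 0.82 in endothelial cells and 1.33 in fibroblasts, and interferon-stimulated genes 0.90 in fibroblasts and -1.26 in monocyte-macrophages.

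Monocyte-macrophages (799 to 2801 cells, 4309911 to 29064202 UMIs per library) had lower summed levels of interferon-stimulated genes and higher levels of cell cycle genes after LPS. Of 25 interferon-stimulated genes 16 fell and none rose (24 lower adjusted over the list alone; median -1.26, camera adjusted p = 9.75e-16; adjusted p = 0.435 with an estimated correlation), with Rtp4 at -2.21 ± 0.52, Oasl2 at -1.91 ± 0.49 and Usp18 at -1.88 ± 0.43. Of 25 cell cycle genes 13 rose (21 adjusted over the list alone; median 1.34, adjusted p = 6.77e-10; adjusted p = 0.478 with an estimated correlation), led by Ccnb2 (2.15 ± 0.49) and Birc5 (1.92 ± 0.45). MHC class II genes, which present peptides to CD4 T cells, fell in 4 of 11 cases (9 adjusted over the list alone; median -1.28, adjusted p = 1.24e-06; adjusted p = 0.448 with an estimated correlation), H2-DMa from 260 ± 39.9 to 131 ± 58.9 CPM. Markers of dendritic cells, which are rich in MHC class II, also fell in this class, from 122 ± 20.6 to 33.8 ± 26.5 CPM (3 of 8 called), so fewer such cells in it may account for part of this fall. Of 22 NF-kB target genes 7 fell, including Tnf (-1.51 ± 0.34), and 1 rose, Irak3 (1.11 ± 0.20), a brake on Toll-like receptor signalling (12 and 2 adjusted over the list alone; median -0.59, adjusted p = 4.48e-05; adjusted p = 0.435 with an estimated correlation). Among single genes Saa3 rose by 5.92 ± 1.17 (adjusted p = 0.0176) and the formyl peptide receptor Fpr1 (ENSMUSG00000045551, chromosome 17, 17876471 to 17883940) by 2.16 ± 0.38 (adjusted p = 0.0118). Hsd11b1, which regenerates active glucocorticoid (ENSMUSG00000016194, chromosome 1, 193221634 to 193264075), rose from 18.6 ± 5.13 to 61.0 ± 21.1 CPM (1.72 ± 0.25, adjusted p = 0.00677). The lectin gene Cd209b (ENSMUSG00000065987, chromosome 8, 3917655 to 3926844) fell by 5.29 ± 1.38 (adjusted p = 0.0366). Lyve1, a marker of interstitial macrophages (ENSMUSG00000030787, chromosome 7, 110850607 to 110863239), fell from 130 ± 80.2 to 22.4 ± 12.0 CPM (-2.55 ± 0.65, adjusted p = 0.035). Neutrophil markers in the class were 435 ± 161 CPM in control and 6503 ± 7522 CPM after LPS. Beside them the 16 genes of the neutrophil immaturity list had a median of 3.36 (4 rose and 1 fell, 11 and 1 adjusted over the list alone, camera adjusted p = 0.000366, and adjusted p = 0.5 with an estimated correlation). Cluster 1 held 23.6% and cluster 6 44.8% of the class in control, against 42.9% and 35.3% after LPS. Cluster 10, led by the macrophage genes C1qa and C1qb, went from 29.5% ± 10.5 to 13.8% ± 6.18, so falls of macrophage genes such as Lyve1 may reflect the make-up of the class. Cluster 38, with the division gene Nusap1 among its leading genes, went from 1.60% ± 0.756 to 3.80% ± 2.54, so more dividing cells may account for the rise of cell cycle genes. For the interferon-stimulated and NF-kB target genes, make-up and changes within cells are likewise not separated here. In all 727 genes rose and 669 fell of 12754. The 1396 calls became 874, 219 and 59 without control 1, 2 and 3, 176 and 160 without LPS 1 and 3, and 5006 without LPS 2, which include all 1396. Hsd11b1 kept its call in all 12 alternatives, while Saa3, Fpr1, Cd209b and Lyve1 lost theirs in 2, 1, 6 and 4 of 12.

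Alveolar macrophages (155 to 674 cells, 1558439 to 6647085 UMIs per library) had 87 genes higher and 21 lower of 9776 after LPS. Hspa1b, an inducible heat shock protein 70 gene with a near-identical copy in Hspa1a, so that counts may be split between them (ENSMUSG00000090877, chromosome 17, 34956436 to 34959238), rose from 18.5 ± 6.03 to 59.9 ± 32.6 CPM (log2 fold change 1.65 ± 0.34, adjusted p = 0.0464). Rbm3, the cold-inducible RNA-binding protein (ENSMUSG00000031167, chromosome X, 8138975 to 8145880), rose by 0.68 ± 0.14 (adjusted p = 0.0464) and Supt4a (ENSMUSG00000020485, chromosome 11, 87737552 to 87743623) by 0.68 ± 0.11 (adjusted p = 0.0423). The antioxidant gene Srxn1 (ENSMUSG00000032802, chromosome 2, 152105516 to 152111376) fell by 0.84 ± 0.18 (adjusted p = 0.0464), a call lost with DESeq2-type size factors. Ell2 (ENSMUSG00000001542, chromosome 13, 75706757 to 75772364) fell by 0.76 ± 0.15 (adjusted p = 0.045). Of 15 oxidative stress genes 3 fell (5 adjusted over the list alone), Txnrd1 by 0.75 ± 0.16 and Gclm by 0.55 ± 0.12. The list median was -0.22 (camera adjusted p = 0.00349; adjusted p = 0.32 with an estimated correlation). The 108 calls became 1, 2 and 9 without control 1, 2 and 3, 9 and 1 without LPS 1 and 3, 437 without LPS 2, and 39 with DESeq2-type size factors. Each of these 5 genes lost its call in 5 or 6 of 12 alternatives. Neutrophil markers in the class were 156 ± 20.6 CPM in control and 2104 ± 2893 CPM after LPS (2 of 7 called higher), and NK cell markers 5.16 ± 1.45 and 46.6 ± 18.1 CPM (1 of 1). Over the 6 classes and 32 tested lists, 78 of 182 pairs of list and class passed camera after LPS. With an estimated correlation 0 passed, and the smallest adjusted p was 0.32.

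Dex before LPS was compared with LPS alone, which asks how a reference glucocorticoid altered the injured lung. In alveolar type 2 cells Hspa1b rose from 38.0 ± 6.38 to 142 ± 9.63 CPM (log2 fold change 1.93 ± 0.19, adjusted p = 0.000127). It was the only gene called there of 6560, with 409 at an unadjusted p under 0.05. It had 82 counts in all after LPS and 201 after LPS with Dex. Summed with Hspa1a it went from 94.4 ± 18.7 to 291 ± 65.2 CPM. Over the other classes this sum moved both ways. It went from 222 ± 45.1 to 136 ± 29.9 CPM in endothelial cells and from 12.7 to 10.8 CPM in neutrophils. In fibroblasts it went from 281 to 298 CPM, in alveolar macrophages from 106 to 202 CPM and in monocyte-macrophages from 204 to 265 CPM. An effect of Dex on these genes and a difference in handling between the groups were not separated. In monocyte-macrophages 24 genes rose and 5 fell of 12754. B cell markers in this class went from 49.1 ± 21.0 to 120 ± 35.2 CPM (1 of 5 called higher). Apolipoprotein gene Apoc1 (ENSMUSG00000040564, chromosome 7, 19689481 to 19692660) rose by 1.71 ± 0.28 (adjusted p = 0.0451). Odc1, the first enzyme of polyamine synthesis (ENSMUSG00000011179, chromosome 12, 17544794 to 17551505), rose from 62.3 ± 7.99 to 161 ± 34.4 CPM (1.36 ± 0.20, adjusted p = 0.0446) and Ddt (ENSMUSG00000001666, chromosome 10, 75771230 to 75773414) by 1.25 ± 0.21 (adjusted p = 0.0451). F13a1, a coagulation factor gene (ENSMUSG00000039109, chromosome 13, 36867178 to 37050244), fell from 314 ± 91.9 to 148 ± 15.3 CPM (-1.08 ± 0.19, adjusted p = 0.0492). Cluster 6, which F13a1 leads, went from 35.3% ± 6.80 of the class after LPS to 25.4% ± 2.85 after LPS with Dex, and clusters 10 and 26 from 13.8% and 4.26% to 18.5% and 7.36%. The checkpoint gene Vsir (ENSMUSG00000020101, chromosome 10, 60346851 to 60372684) fell by 0.59 ± 0.10 (adjusted p = 0.0451). In endothelial cells 16 genes rose and 6 fell. The falls included Adamts1, a matrix protease (ENSMUSG00000022893, chromosome 16, 85793827 to 85803113), by 1.11 ± 0.21 (adjusted p = 0.0452) and Epha4 (ENSMUSG00000026235, chromosome 1, 77367185 to 77515088) by 1.02 ± 0.19 (adjusted p = 0.0452). The 29 calls in monocyte-macrophages became 30 without LPS 2, with 16 of the 29 among them, 4 without LPS 3 and 0 without LPS+Dex 1, 2 or 3. DESeq2 called 207 genes higher and 206 lower in this class. With the replicate block Odc1 kept its call, while Apoc1, Ddt, F13a1 and Vsir lost theirs. The call in alveolar type 2 cells was also the only one without LPS 2. The 22 in endothelial cells became 8 without LPS 2, 74 without LPS 3 and 5, 4 and 3 without LPS+Dex 1, 2 and 3. The 7 genes named here for these classes lost their calls in 4 to 7 of 12 alternatives and Hspa1b in none.

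Among the gene lists, MHC class II genes were higher after Dex in endothelial cells (median 0.84, camera adjusted p = 5.35e-16; adjusted p = 0.104 with an estimated correlation). Of 10 genes 1, H2-DMb2 (1.33 ± 0.21), rose, and 9 did adjusted over the list alone. In neutrophils the median was 1.15 (adjusted p = 5.27e-17; adjusted p = 0.104 with an estimated correlation), with 0 of 10 called by edgeR and 8 higher adjusted over the list alone. B cell markers moved with these genes: they were at 196 ± 72.6 CPM in endothelial cells after LPS and 541 ± 16.8 CPM after LPS with Dex, and at 21.3 ± 15.1 and 66.1 ± 8.44 CPM in neutrophils. NF-kB target genes had medians of 0.43 in neutrophils (adjusted p = 2.57e-13; adjusted p = 0.25 with an estimated correlation) and 0.54 in fibroblasts (adjusted p = 4.06e-07; adjusted p = 0.25 with an estimated correlation). Of 22 genes 0 were called in either class, and 5 and 6 were higher adjusted over the list alone. Il1b in neutrophils was at 4626 ± 879 CPM after LPS, 8371 ± 1287 CPM after LPS with Dex (adjusted p = 0.441) and 7367 ± 185 CPM in control. Cluster 3 held 32.7% ± 24.5 of the neutrophils after LPS and 66.2% ± 4.64 after LPS with Dex. Cluster 14 held 27.9% ± 47.0 and 0.416% ± 0.362, so make-up and changes within neutrophils are not separated here. Interferon-stimulated genes in monocyte-macrophages had a median of -0.76 (adjusted p = 9.7e-10; adjusted p = 0.446 with an estimated correlation). Of them 0 of 25 were called and 14 were lower adjusted over the list alone. Without LPS 2 the median was -0.30. The list of glucocorticoid-responsive genes passed camera in none of the 6 classes, with adjusted p between 0.101 and 0.906 and medians between -0.08 and 0.30. Dex was given 1 h before LPS and lungs were collected after 72 h, so a response that had passed by then would not be seen. In fibroblasts, neutrophils and alveolar macrophages edgeR called 0 genes, with 1627, 638 and 815 at an unadjusted p under 0.05 and 148, 21 and 5 by DESeq2. Without LPS 2 these counts stayed at 0. Without LPS 3 the neutrophil count was 39.

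TMP before LPS was compared with LPS alone in the same way. Hspa1b fell from 94.9 ± 11.4 to 13.8 ± 2.92 CPM in monocyte-macrophages (log2 fold change -2.78 ± 0.33, adjusted p = 0.00816) and from 59.9 ± 32.6 to 5.61 ± 1.13 CPM in alveolar macrophages (-3.29 ± 0.48, adjusted p = 0.032). Hspa1a (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156) fell from 109 ± 20.4 to 20.0 ± 4.60 CPM in monocyte-macrophages (-2.44 ± 0.30, adjusted p = 0.00957). In alveolar macrophages Zfp36l2, an mRNA decay factor (ENSMUSG00000045817, chromosome 17, 84183931 to 84187947), fell by 0.68 ± 0.10 (adjusted p = 0.032). In endothelial cells 10 genes rose and 5 fell. The endothelin receptor gene Ednrb (ENSMUSG00000022122, chromosome 14, 103814625 to 103844402) fell from 485 ± 234 to 173 ± 47.0 CPM (-1.51 ± 0.28, adjusted p = 0.0488). Sirpa (ENSMUSG00000037902, chromosome 2, 129592835 to 129632228) fell by 1.61 ± 0.26 (adjusted p = 0.0393), while Tmsb10, an actin-binding thymosin (ENSMUSG00000079523, chromosome 6, 72957347 to 72958748), rose by 0.69 ± 0.12 (adjusted p = 0.0393). The 15 endothelial calls became 5 without LPS 2, 43 without LPS 3 and 4, 0 and 1 without LPS+TMP 1, 2 and 3. None was left with doublets kept or with the replicate block, while DESeq2 called 59 genes higher and 45 lower. The 3 alveolar macrophage calls became 0 without LPS 1, LPS+TMP 2 or LPS+TMP 3 and 8 without LPS 2, and the 5 monocyte-macrophage calls 7 without LPS 2 and 0 without LPS+TMP 2. The calls of Hspa1b and Hspa1a in monocyte-macrophages were lost in 2 of 12 alternatives and those of the other genes in 5 to 7.

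**Figure D4:**
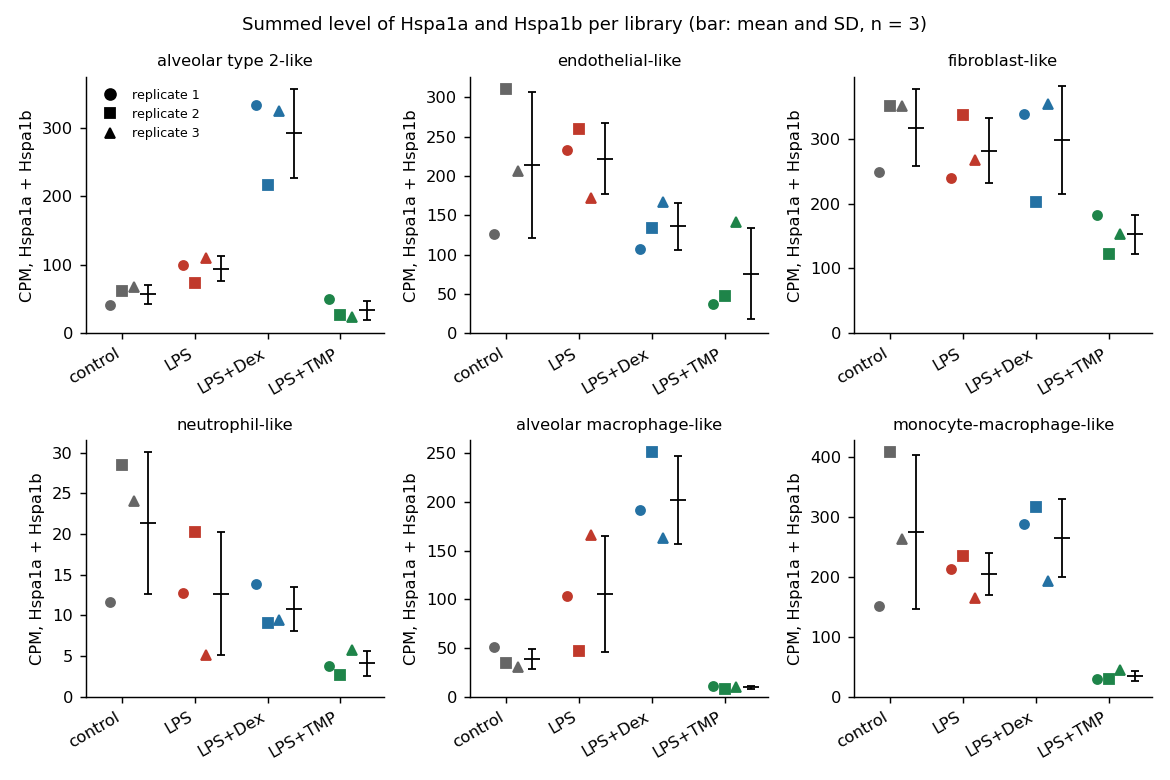
Summed level of Hspa1a and Hspa1b in CPM per library in 6 cell classes by group; symbols are libraries and bars give the mean and SD of 3. In monocyte-macrophages the mean is 204 CPM in LPS and 34.3 CPM in LPS+TMP, and in alveolar macrophages 106 and 9.53 CPM.

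Aerocyte genes had a median of -0.79 after TMP in endothelial cells (camera adjusted p = 1.04e-10; adjusted p = 0.246 with an estimated correlation), with 1 of 10, Ednrb, called and 8 lower adjusted over the list alone. Cluster 30, with Ednrb among its leading genes, held 21.0% ± 6.97 of the endothelial cells after LPS and 12.3% ± 2.16 after LPS with TMP. MHC class II genes in this class had a median of 0.70 (adjusted p = 2.48e-08; adjusted p = 0.246 with an estimated correlation), with 0 of 10 called and 5 higher adjusted over the list alone. B cell markers in it were at 196 ± 72.6 CPM after LPS and 612 ± 176 CPM after LPS with TMP. Immediate early genes had a median of -0.34 in alveolar macrophages (adjusted p = 1.21e-07; adjusted p = 0.326 with an estimated correlation) and 0.34 in fibroblasts (adjusted p = 1.26e-07; adjusted p = 0.452 with an estimated correlation). Of 18 genes 0 were called in either class, while 6 were lower and 2 higher adjusted over the list alone. Fos in alveolar macrophages was at 852 ± 288 CPM after LPS and 345 ± 43.1 CPM after LPS with TMP (adjusted p = 0.0727). NF-kB target genes in alveolar macrophages had a median of 0.51 (adjusted p = 4.99e-09; adjusted p = 0.353 with an estimated correlation), with 0 of 22 called and 6 higher adjusted over the list alone. In alveolar type 2 cells, fibroblasts and neutrophils edgeR called 0 genes, with 495, 798 and 417 at an unadjusted p under 0.05 and 0, 13 and 5 by DESeq2. Without LPS 2 the counts in these 3 classes were again 0. Without LPS 3 the neutrophil count was 200.

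The direct comparison of the pretreatments, LPS with TMP against LPS with Dex, gave 8 calls of a gene in a class, for 5 genes, all lower after TMP. Hspa1b fell by 3.52 ± 0.26 on the log2 scale in alveolar type 2 cells (adjusted p = 2.37e-06), from 142 ± 9.63 to 12.4 ± 0.478 CPM, and by 3.18 ± 0.33 in monocyte-macrophages (adjusted p = 0.00487). The alveolar type 2 values rest on 201 counts in all after LPS with Dex and 14 after LPS with TMP. The SD and SE from so few counts may understate the spread between animals. Summed with Hspa1a, the levels there were 291 ± 65.2 and 33.5 ± 14.2 CPM. Hspa1a fell by 4.66 ± 0.52 in alveolar macrophages (adjusted p = 0.000787), from 102 ± 25.4 to 4.01 ± 1.53 CPM. The other 5 calls, named after their values were seen, were Hspa1a, Apoc1 and Hist4h4 in monocyte-macrophages and Hspa1b and Mt2 in alveolar macrophages. In endothelial cells, fibroblasts and neutrophils edgeR called 0 genes, with 553, 842 and 785 at an unadjusted p under 0.05 and 7, 21 and 27 by DESeq2. Without LPS+Dex 3 the endothelial count was 4. The 4 monocyte-macrophage calls became 0 without LPS+TMP 1 and 2 without LPS+TMP 3, and the 1 alveolar type 2 call became 3 without LPS+Dex 2. Immediate early genes had medians of 0.55 in fibroblasts (camera adjusted p = 1.1e-14; adjusted p = 0.386 with an estimated correlation) and 0.63 in endothelial cells (adjusted p = 7.08e-13; adjusted p = 0.41 with an estimated correlation). Of 18 and 17 genes 0 were called, and 3 and 2 were higher adjusted over the list alone. Aerocyte genes in endothelial cells had a median of -0.68 (adjusted p = 4.18e-12; adjusted p = 0.29 with an estimated correlation), with 0 of 10 called and 5 lower adjusted over the list alone. Cluster 30, with Ednrb among its leading genes, moved with them. It held 23.7% ± 4.18 of the endothelial cells after LPS with Dex and 12.3% ± 2.16 after LPS with TMP.

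Whether Dex and TMP moved the same genes, and whether they moved genes back towards control, was read from fold changes across genes, which are not independent replicates. Because these contrasts share the LPS libraries, each value stands beside simulated libraries without any group effect. The simulations drew genes independently, with the same spread per gene in all groups. The real LPS libraries differed more from each other (chi-square per degree of freedom 757.5 to 1519) than the controls did (109.1 to 265.9). The simulated values may therefore understate what sharing alone gives, and an excess over them is no test of a shared effect. The changes by Dex and by TMP correlated at r = 0.288 to 0.580 over the 6 classes, against 0.396 to 0.529 in the simulations. The covariance exceeded the simulated one by a median of 0.0295 (range -0.00658 to 0.0824). Without LPS replicate 2 that median was 0.0196 (-0.00167 to 0.0724), while r was 0.315 to 0.591 against 0.501 to 0.623 simulated. The LPS effect and the Dex effect correlated at -0.0871 to 0.274, against -0.518 to -0.419 simulated, with a covariance difference of 0.0964 (0.0227 to 0.164). For the LPS effect and the TMP effect r was -0.214 to 0.257, against -0.550 to -0.402 simulated, with a covariance difference of 0.0634 (0.00134 to 0.165). Without LPS replicate 2, and beside simulations of the remaining 11 libraries, this difference was 0.00605 (-0.0680 to 0.0884) for Dex and -0.0238 (-0.0812 to 0.0290) for TMP, so its size rests on that library. In endothelial cells 7 genes rose with both Dex (16 genes) and TMP (10 genes). All 7 lay 6.33 to 33.2 times higher in B cells, so they may come from B cell RNA and cannot be read as a shared effect on endothelial cells. Among genes changed by LPS and moved the other way by a pretreatment, Hspa1b in alveolar macrophages with TMP was 1 of only 3 such calls. There it went past the control level of 18.5 ± 6.03 CPM, to 5.61 ± 1.13 CPM after TMP, so it was not a return to control. With 3 LPS libraries the shared ones cannot be split, so part of the correlations and covariances may come from sharing them.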

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

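The tests of the label, mixture, digestion and free RNA explanations, that of the share of B cell genes, and the splits were chosen only after the results were seen; the ratio test for B cell RNA was chosen before. Each of 4 gene list results stood out because, in every library, the list moved one way in 1 cell class and the other way in another, as the difference between a library and the mean of the reference group. None of these differences was tested. Against control, LPS moved interferon-stimulated genes by a mean of -0.251 (log2) in endothelial cells and 0.863 in fibroblasts, a difference of -1.114, and by -1.267 in monocyte-macrophages, which lies 2.13 from the fibroblast value. Genes of neutrophil activation and ageing moved by 0.747 in fibroblasts and -0.456 in neutrophils, a difference of 1.203. With TMP against LPS, immediate early genes moved by 0.391 in fibroblasts and -0.359 in alveolar macrophages, a difference of 0.75.

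LPS replicate 2 lay nearer to the controls than the other LPS libraries in all 6 classes. A label swapped with a control needs a control among the treated libraries, and the highest position of a control was 0.285, which argues against it. An untreated animal with a wrong label should lie within the range of the controls, but this library lay above the highest control in 6 of 6 classes. In neutrophils it lay at 0.440 against 0.148, more than the range of the controls above them, which argues against it. The gap was small in endothelial cells (0.138 against 0.121) and alveolar type 2 cells (0.204 against 0.184). A mixture of cells from an untreated and a treated animal should bring all LPS-associated cells in 1 proportion. Relative to the other LPS libraries, LPS replicate 2 held 0.0399 as many such neutrophils and 0.0492 as many such B cells. For NK cells of cluster 22 the ratio was 0.393, so the range was 9.842-fold. This cannot decide, because the proportions also differed between LPS 1 and LPS 3. These held 1624 and 3837 such neutrophils, 1284 and 666 such B cells, and 221 and 176 such NK cells. A mixture therefore stays open. A weaker or slower response of the animal of LPS replicate 2, or a smaller received dose, also stays open as a hypothesis and was not tested.

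Hspa1a and Hspa1b together were lower after TMP than after LPS alone in 6 of 6 class means, with no overlap between the libraries in 5. In each class the mean after TMP also lay below that of the controls. It was 34.3 ± 8.59 against 274 ± 128 CPM in monocyte-macrophages and 33.5 ± 14.2 against 56.7 ± 14.2 CPM in alveolar type 2 cells. Less stress during digestion should lower the immediate early genes too; their median change was above 0 in alveolar type 2, endothelial and fibroblast cells, the lowest being 0.236. The difference between the libraries of the groups was within 2 SE of 0 in alveolar type 2 (0.329 ± 0.239) and endothelial cells (0.217 ± 0.189). In fibroblasts (0.386 ± 0.158) it was beyond 2 SE, though the list had an adjusted p of 0.452 with an estimated correlation. Digestion therefore stays open in these classes too. In alveolar macrophages and monocyte-macrophages it was below 0 in both, the higher being -0.338, but the difference between the libraries of the groups was beyond 2 SE of 0 only in the former (-0.341 ± 0.067, against -0.374 ± 0.294 in monocyte-macrophages), while other heat shock genes had medians of 0.005 and -0.047. Digestion and TMP cannot be told apart there, because lungs of 1 group may have been digested together and the labels name no batches. Less free RNA should take a similar amount from all classes, but monocyte-macrophages lost 13.39 times the whole level found in neutrophils after LPS (12.7 CPM), which argues against it. An effect of TMP on heat shock gene expression and a difference in handling between the groups both stay open.

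B cell genes were higher in endothelial cells after Dex and after TMP than after LPS alone. RNA of B cells, free or in mixed droplets, should account for most genes called higher there: 17 of 19, or 89.47%, lay at least 4 times higher in B cells than in endothelial cells. It should also bring all these genes in 1 ratio to their level in B cells, and that ratio ran from 7.16% to 19.6%, a 2.737-fold range. Both results are in line with B cell RNA, and no biological explanation was tested. The called rises in endothelial cells after either pretreatment, and the higher MHC class II medians there, may therefore belong to B cells.

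The 6 libraries of a contrast can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05, so only the real count and the highest other are given. For LPS against control as many genes were called in 1 of 10 splits, the real one, in endothelial cells (18 real, 2 highest other), fibroblasts (10 and 0), neutrophils (1911 and 0), alveolar macrophages (108 and 8) and monocyte-macrophages (1396 and 1026), and in all 10 for alveolar type 2 cells (0 and 0). The split with 1026 calls exchanged LPS replicate 2 with control 1. For LPS+Dex against LPS the numbers were 1 split in endothelial cells (22 and 1) and monocyte-macrophages (29 and 3), 3 splits in alveolar type 2 cells (1 and 1) and all 10 in fibroblasts (0 and 1), neutrophils (0 and 0) and alveolar macrophages (0 and 1). For LPS+TMP against LPS they were 2 splits in endothelial cells (15 and 76) and monocyte-macrophages (5 and 6), 3 in alveolar macrophages (3 and 8) and 10 in alveolar type 2 cells (0 and 17), fibroblasts (0 and 11) and neutrophils (0 and 1378). The split with 1378 calls set LPS 1, LPS 2 and LPS+TMP 3 apart, and that with 76 set LPS 1, LPS+TMP 2 and LPS+TMP 3 apart, so both point to a structure of the samples other than the groups. In the former, LPS 1, LPS 2 and LPS+TMP 3 had medians of 3606, 2961 and 4680 UMIs per neutrophil. LPS 3, LPS+TMP 1 and LPS+TMP 2 had 7343.5, 7774 and 6529. They also held more neutrophils of cluster 7 (2576, 1287 and 381, against 220, 19 and 121). Depth and make-up were not separated here. For LPS+TMP against LPS+Dex the numbers were 1 split in alveolar type 2 cells (1 and 0), alveolar macrophages (3 and 1) and monocyte-macrophages (4 and 0), and 10 in endothelial cells (0 and 46), fibroblasts (0 and 11) and neutrophils (0 and 0). The 46 calls likewise point to structure among those libraries. For shares, in the order of the contrasts above, the real counts were 0, 8, 2 and 3 and the highest others 1, 0, 1 and 0. For pairs of list and class the real counts were 78, 60, 63 and 56 and the highest others 69, 68, 59 and 52, so splits that mix the groups call more pairs than the real one for LPS+Dex against LPS, and almost as many in the other contrasts, with the preset correlation. In B, T and NK cells after LPS the real counts were 2447, 117 and 2114 and the highest others 1952, 0 and 0.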

How the results depend on the processing

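Results without LPS replicate 2 for lists and correlations, shares among structural cells, the alternatives of the test over 4 groups and B, T and NK cells were chosen after the data were seen; all other alternatives were planned. Of 466 results of named genes under an alternative, 320 kept their direction and call, 146 kept the direction and lost the call, and 0 reversed. Of 39 named gene results 8 kept their call under every alternative. DESeq2 moved 22 of 24 counts of called genes, dropping the filter on low counts 18 and changing the size factors 1. The stricter cell filter moved 1 of 29 results, keeping doublets 5 of 29, and the Leiden resolution of 0.5 moved 0 of 5 results. Where a count moved by over 1.5 times the cause was not tested, except that no filter tests more genes and leaving out a library leaves fewer samples. Contrasts are ordered LPS against control, LPS+Dex against LPS, LPS+TMP against LPS and LPS+TMP against LPS+Dex.

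DESeq2 called 40, 6 and 4 genes in alveolar type 2 cells (first, second and last contrast), 147, 76, 104 and 7 in endothelial cells, 204, 148, 13 and 21 in fibroblasts, 21, 5 and 27 in neutrophils (last 3 contrasts), 215, 5, 29 and 10 in alveolar macrophages and 2167, 413, 91 and 36 in monocyte-macrophages. Without the filter on low counts edgeR called 250, 91, 112 and 87 in alveolar type 2 cells, 572, 245, 225 and 84 in endothelial cells, 116, 1 and 1 in fibroblasts (all but LPS+TMP against LPS), 18 and 34 in neutrophils (second and last), 589, 181, 222 and 126 in alveolar macrophages and 56 in monocyte-macrophages (second). DESeq2-type size factors left 39 calls in alveolar macrophages after LPS. The stricter cell filter gave 4 in alveolar type 2 cells after LPS. With doublets kept, 2 genes were called in alveolar type 2 cells (second contrast) and 4, 55, 0 and 3 in endothelial cells.

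The replicate numbers do not pair the samples: same-numbered libraries had mean correlations of their deviations between -0.0653 and -0.00683 over the 6 classes. With the replicate block the counts that moved were 6 in alveolar type 2 cells and 4 in fibroblasts after LPS, 14 for LPS+Dex and 0 for LPS+TMP against LPS in endothelial cells, 0 in alveolar macrophages (LPS+TMP against LPS), 1 and 2 in monocyte-macrophages (second and last) and 5 classes of cells (second); list calls were 79, 60, 67 and 55.

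Leaving out 1 library at a time gave 0 to 57 calls in alveolar type 2 cells, 0 to 677 in endothelial cells, 0 to 367 in fibroblasts, 410 to 3883 in neutrophils, 1 to 437 in alveolar macrophages and 59 to 5006 in monocyte-macrophages for LPS against control, the highest always without LPS 2. For LPS+Dex against LPS the ranges were 1 to 3 in alveolar type 2 cells, 3 to 74 in endothelial cells, 0 to 39 in neutrophils and 0 to 30 in monocyte-macrophages. For LPS+TMP against LPS they were 0 to 43 in endothelial cells, 0 to 200 in neutrophils, 0 to 8 in alveolar macrophages and 0 to 7 in monocyte-macrophages, and for LPS+TMP against LPS+Dex 1 to 3 in alveolar type 2 cells, 0 to 4 in endothelial cells, 2 to 3 in alveolar macrophages and 0 to 4 in monocyte-macrophages. Counts of classes with a changed share ranged from 0 to 6, 1 to 8, 2 to 3 and 2 to 3, and the test over 4 groups from 1 to 9.

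TMM scaling of the class counts gave 2 classes for LPS against control and 5 for LPS+TMP against LPS+Dex; shares among structural cells gave 1, 2 and 4 for the first 3 contrasts. Of the list calls 0 held in any contrast with an estimated correlation, and fry called 18, 5, 0 and 0; without LPS 2 camera called 73, 52 and 58 in the first 3 contrasts. Correlations and covariances of changes were read against simulations of the same libraries. Without LPS 2 the median covariance difference of the LPS changes with the TMP changes reversed from 0.0634 to -0.0238, and that with the Dex changes went from 0.0964 to 0.00605. The median correlations went from 0.039 to -0.303 and from 0.132 to -0.159, still above the simulated values. That of the Dex and TMP changes reversed against the simulated values, from 0.446, above them in the median over classes, to 0.474, below them. The causes were not tested.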

Other observations

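All tests in this part were chosen after the data were seen. Lymphocytes, for which no gene tests had been planned, also differed after LPS. In NK cells (389 to 1736 per library) edgeR called 1392 genes higher and 722 lower, and genes of division were among the rises: Ube2c rose by 6.20 ± 0.59 (log2, SE, n = 3, adjusted p = 0.000159), Cenpf by 5.36 and the histone gene Hist1h3c by 4.89, while Kcnj8 fell by 2.53 and Abcg1 by 1.80. In B cells (996 to 4063 per library) 1771 genes rose and 676 fell, with Zbtb32, a regulator of B cell responses, at 5.14 ± 0.81 (adjusted p = 0.0168), Birc5 at 4.74 and Cdca8 at 3.85 among the rises, and Rasgef1b (-1.73, adjusted p = 0.0418) and the complement receptor Cr2 (-1.68, adjusted p = 0.0209) among the falls. T cells had 97 rises and 20 falls, including the cytotoxic granule gene Gzmb (3.23 ± 0.56, adjusted p = 0.034), Ube2c (2.18) and Birc5 (2.15) among the rises and Itm2a (-1.04) and Cd40lg (-0.84) among the falls. Their make-up shifted too: cluster 4, led by Lef1 and Tcf7, held 72.8% ± 3.12 of the T cells in control and 53.4% ± 11.3 after LPS, and cluster 36, led by Cd8b1, 1.59% ± 0.677 and 9.63% ± 6.05, so make-up and changes within T cells are not separated here. DESeq2 called 1347 and 718 in NK cells, 2271 and 943 in B cells, and 395 and 55 in T cells, and without LPS replicate 2 edgeR called 2413 and 2086, 3860 and 3202, and 1202 and 762. In NK cells cluster 22 held 0.534% ± 0.303 of the class in control and 15.9% ± 9.93 after LPS, so its make-up and changes within its cells are not separated here. The make-up of the B cells shifted as well: cluster 0, led by Fcer2a, held 98.5% ± 0.592 of them in control and 56.9% ± 34.8 after LPS, and clusters 2 and 9, the latter led by division genes, held 28.2% and 14.9% after LPS. After TMP the heat shock gene Hspa1b was also lower in NK cells than in LPS (-4.10, adjusted p = 0.0149) and than in LPS with Dex (-4.85, adjusted p = 0.00186). It was not called against LPS in B cells (-2.51, adjusted p = 0.613) or T cells (-1.73, adjusted p = 0.793), nor against LPS with Dex (-3.07, adjusted p = 0.808, and -2.42, adjusted p = 1.00).

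Cells of squamous epithelium, a tissue outside the alveoli, appeared in some libraries. The cluster led by Krt14, Krt5, Krt15 and H19 held 3.68%, 6.99% and 2.29% of the cells in control 1, 2 and 3, 2.08% in LPS 1, 1.20% in LPS+TMP 1 and 1.18% in LPS+TMP 3. In each of the other 6 libraries it held at most 2 cells. In endothelial cells Krt15 and Sfn, markers of such epithelium, were among the 7 genes called lower after LPS. Tef (by 1.97) and Nr1d1 (by 2.49) were called higher after LPS in endothelial cells and Dbp (by 1.97) in fibroblasts. These genes have a daily rhythm, but no list of such genes was tested, and the time of day of collection was not used here.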
